A study of Homo sapiens with 12 samples.

How the data were processed

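RNA from HaCaT cells, an established line of immortalised human skin keratinocytes, was sequenced in 12 libraries, 2 in each of 6 groups. Per the labels, the cells were either unexposed or had been exposed to UVB 10 times about a week apart, and each kind was left without compound or given SFN or UA. The series title names SFN as sulforaphane; UA is not spelled out in the labels and is called UA here. The labels give the UVB dose as 10 mJ per square centimetre for each sample, while the treatment protocol writes the same number with another unit, and they give the compound dose as 10 mM, a unit that may be a typing error for micromolar. The time between the last exposure, the compound and the harvest is not given in the sources used here. Each library's group and replicate number were taken from its title. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

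The values used are counts of read pairs per gene that the authors deposited as 1 table of 26364 genes and 12 libraries. Per the file headers, the counts were made with featureCounts 1.6.3 in paired-end mode on primary alignments, without a strand setting, against a UCSC gene annotation of the human genome build hg19, from sorted alignments with duplicates removed. The submitters' processing notes also name HISAT2, Picard and DESeq2, without versions. The command in the header names 16 alignment files and the table holds 12 libraries; the others were not analysed here. Removing duplicates without molecular identifiers takes away true molecules of abundant genes along with copies, so differences of very abundant genes can be understated. Without strand, reads of overlapping and antisense genes cannot be told apart. Reads shared by near-identical genes (the AKR1C genes, KRT6A, KRT6B and KRT6C, metallothioneins, SERPINB3 and SERPINB4, PSG genes, histone genes) can be split or lost in counting, and values of single members are uncertain for that reason. Per the file headers, the deposited table also gives the summed exon length of each gene in bases, which was used only in a check of length.

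Depth was 17829712 to 27700272 counts per library. Of the genes in the table, 5046 had no counts in any library, and edgeR's filterByExpr kept 15115 for testing. The fit was made in R 4.3.3 with edgeR 4.0.16: TMM normalisation, robust dispersions and the robust quasi-likelihood test, with 1 coefficient per group over all 12 libraries, so that all groups share the estimate of spread. The biological coefficient of variation of the fit was 0.125. Every adjusted p of a gene is from this test with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. Levels are CPM, counts scaled to a common library size with TMM factors, given as mean ± SD of n = 2 libraries. For genes with few counts in 1 group, the ratio of pooled counts is given with an exact 95% interval. Such intervals cover counting error only, since the reads carry no molecular identifiers.

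There were 11 comparisons: UVB against control, each compound against its own no-compound group in unexposed and in exposed cells, exposed against unexposed cells within each compound, the interaction of each compound with UVB, and SFN against UA in unexposed and in exposed cells. Before the data were examined, 29 gene lists were written, covering NRF2 targets, heat shock, ER stress with the ATF4 response, cholesterol synthesis, p53 targets, repair of UV lesions, mitosis, DNA replication, inflammation, interferon response, keratinocyte differentiation, basal keratinocyte genes, mesenchymal genes, matrix proteolysis, immediate early genes, DNA methylation enzymes, histone-modifying enzymes, aryl hydrocarbon receptor (AHR) targets, metallothioneins, hypoxia with glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, keratinocyte activation, senescence, replication-dependent histones, and markers of fibroblasts, melanocytes, leukocytes and endothelial cells. The members of the mitochondrial list have 0 entries in the table, and the melanocyte and leukocyte lists had 2 tested members each, under the minimum of 3, so 26 lists were tested. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Counts of called members are over all genes tested, with the count adjusted over the list alone beside them.

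Genes were named by a rule fixed before the data were examined. For each of the 5 main comparisons it takes the 6 largest rises and 6 largest falls among called genes with at least 5 CPM in the higher group and no overlap between libraries, 11 genes chosen for their known roles, and up to 4 members per list with the lowest adjusted p. For the other comparisons it takes 3 in each direction. Of the list members so picked, those whose call held with each library left out were preferred as examples, a choice made after the values were seen. For 1 gene so picked, the result is not reported here, and the counts of named calls leave it out. Genes named outside the rule, S100A8 and S100A9 after UVB and CHAC1, NQO1, SRXN1 and GCLM in the interactions, were chosen after their values were seen.

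Alternatives fixed before the data were examined were DESeq2's size factors and upper quartile scaling, no filter and a stricter filter on low counts (5 CPM in 2 libraries), DESeq2 1.42.0 and limma-voom in place of edgeR, non-robust estimation, only the groups compared in the fit, the replicate number as a block, stricter thresholds, and each library left out in turn. A library left alone in its group was assumed to vary like the others. In a test on simulated data with known answers, made for UVB against control over 14813 genes with 196 changed, edgeR recovered 29.7% of genes changed 1.5-fold, 69.7% of those changed 2-fold and 90.9% of those changed 4-fold, with 5 false calls. For the SFN by UVB interaction it recovered 6 of 130, 72 of 133 and 105 of 131 genes at these folds (4.62%, 54.1% and 80.2%), with 15 false calls. A simulated raised list of 25 genes was called by camera with the preset (adjusted p = 1.63e-53) and the estimated correlation (0.000277) and by fry (0.000191). Of 20 unchanged lists camera called 1 with the preset correlation and 0 with the estimated one, and fry 0. The simulated genes varied independently, so this does not test lists whose members vary together. Each gene had the same dispersion in every group, so the shares recovered leave out the wider spread of the UA libraries. A simulated raise of chromosome 14 was found in 9 of 9 windows, and 0 of 279 others passed.

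The place of changed genes along chromosomes was examined after the first results were seen. Tested genes were ordered by start position (hg19, as in the table) and divided into 289 windows of 50 neighbouring genes. A window was taken as shifted when its median log2 fold change, relative to all genes, passed a bound that 95% of 1000 shuffles of gene positions stayed under in every window.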

Results

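The transcriptome of HaCaT keratinocytes was measured in 6 groups of 2 libraries. Unexposed cells were left without compound (control) or given SFN or UA. Cells exposed 10 times to UVB were left without compound (UVB) or given SFN (UVB+SFN) or UA (UVB+UA). SFN is sulforaphane, a compound of broccoli known to activate the antioxidant regulator NRF2. The libraries held 27700272 and 25990334 counts in control, 21803359 and 19471123 in SFN, 20994356 and 19821358 in UA, 18533081 and 17829712 in UVB, 26338276 and 26212244 in UVB+SFN, and 20657876 and 18419129 in UVB+UA. The first principal component (44.3% of the variance) parted exposed from unexposed cells, the second (20.7%) the UA groups from the rest, and the third (18.5%) the SFN groups. Replicates correlated at 0.99 to 0.995 in 5 groups and at 0.979 in UA (log2 CPM across genes, which are not independent replicates). The UA libraries differed over 2-fold in 1320 genes, against 204 to 647 genes in the other groups.

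**Figure D1:**
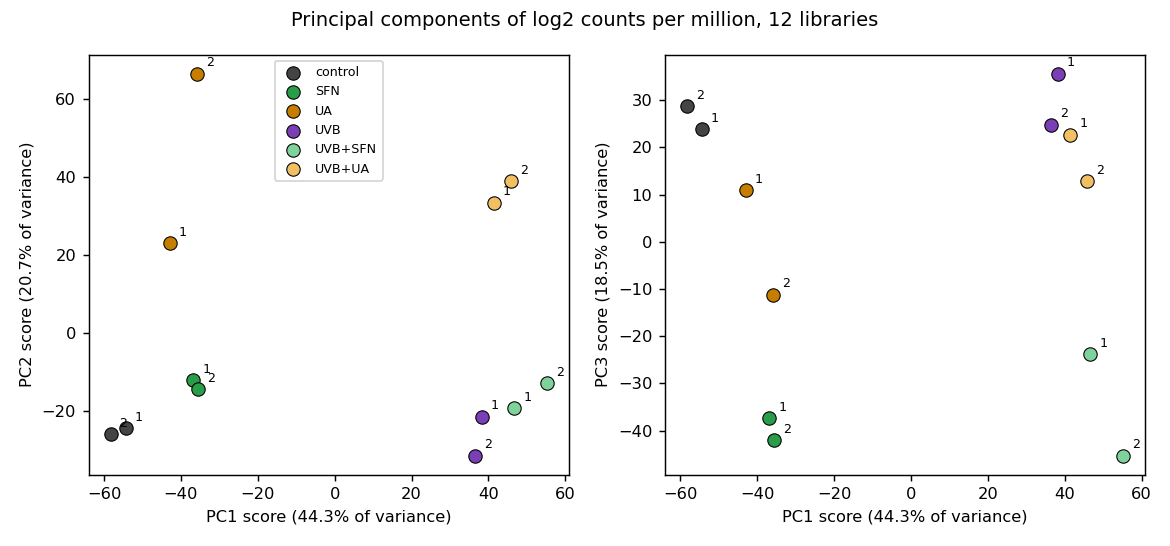
Scores of the 12 libraries on the first 3 principal components of log2 CPM, each point a library with its replicate number, coloured by group. Exposed libraries lie at 36.5 or more on the first component and unexposed ones at -35.6 or less, and on the second UA replicate 2 lies at 66.4 and UA replicate 1 at 23.1.

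The first comparison asks how cells repeatedly exposed to UVB differed from unexposed ones. Genes of keratinocyte activation, switched on in wounded and inflamed epidermis, were higher after UVB: 9 of 12 members rose and 0 fell (11 and 0 adjusted over the list alone), with a median log2 fold change of 2.82. The wound keratin KRT17 rose from 648 ± 19.3 to 1951 ± 639 CPM (library-scaled counts, mean ± SD, n = 2). The protease inhibitors SERPINB3 (0.385 ± 0.0594 to 4.59 ± 0.494 CPM) and SERPINB4 (log2 3.37 (SE 0.42)) rose, as did KRT6B (log2 2.28 (SE 0.34)), which shares sequence with KRT6A and KRT6C. The alarmins S100A8 and S100A9, chosen after their values were seen, were at 0.0191 ± 0.027 and 0.0928 ± 0.0305 CPM in control and at 1.92 ± 1.34 and 3.67 ± 2.12 after UVB. The call of S100A8 (adjusted p = 0.00789; 0.00313 for S100A9) ended when a library was left out (control replicate 1 0.0584, UVB replicate 2 0.0551). The list stood apart from other genes by camera (adjusted p = 4.3e-07, and adjusted p = 0.0262 with an estimated correlation).

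**Figure D2:**
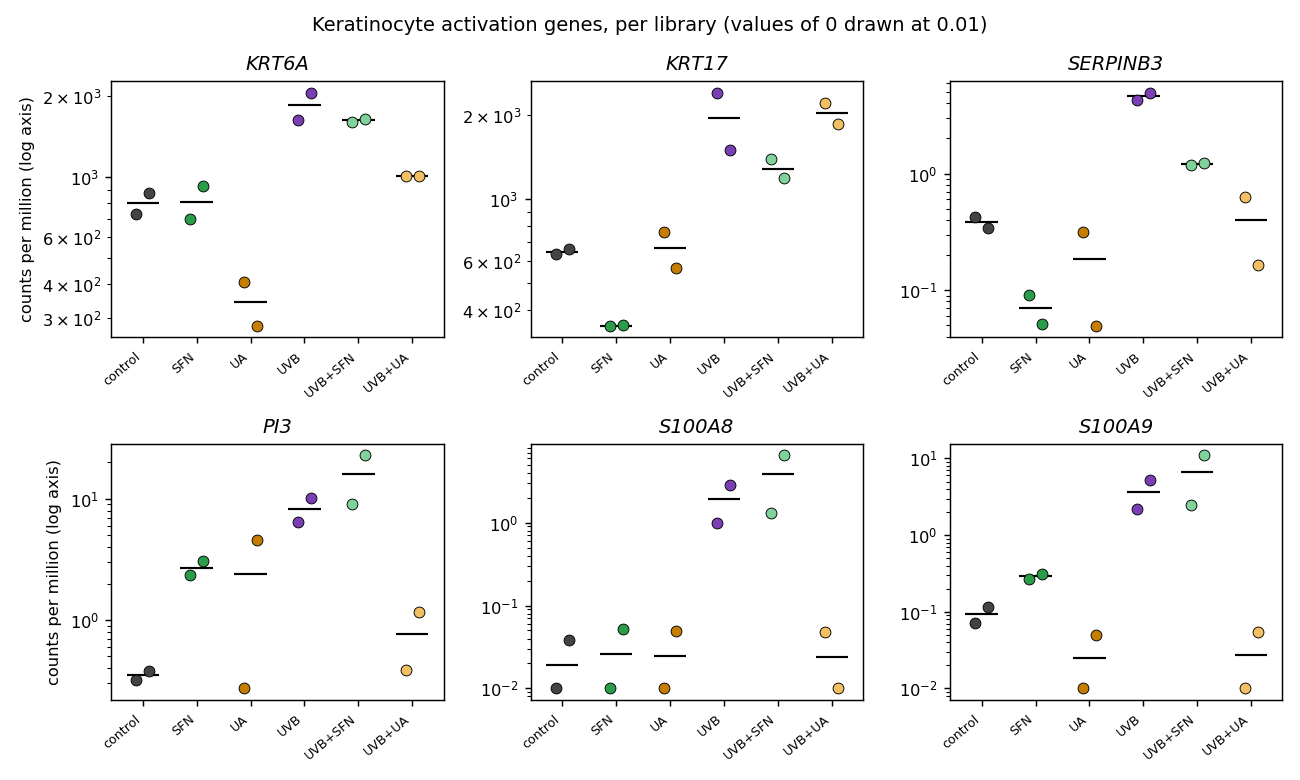
Level of 6 keratinocyte activation genes in each library, in CPM on log axes; points are libraries, bars are group means, and values of 0 are drawn at 0.01. SERPINB3 averaged 0.385 in control, 4.59 after UVB, 1.22 with UVB+SFN and 0.397 with UVB+UA.

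After UVB, 2199 genes were higher and 2286 lower of 15115 tested (edgeR, adjusted p under 0.05), and 669 and 878 of them differed at least 2-fold. The largest rises, given as ratios of pooled counts with 95% counting intervals, were ARHGEF6 on chromosome X from 135747712 to 135863503 (125, 48.4 to 462), TSHZ3 (58.7, 30.5 to 129), LINC00665 (55.6, 25.1 to 153) and RIBC2 (45.7, 23.7 to 101). With them rose CCNA1, cyclin A1 (0.22 ± 0.0414 to 11.8 ± 2.11 CPM), and TNFRSF11B, the decoy receptor osteoprotegerin (0.239 ± 0.0144 to 9.93 ± 2.52 CPM). The largest falls were the endocytosis gene SH3GL2 on chromosome 9 from 17578952 to 17797126 (218, 85 to 802), FMN2 (202, 35.9 to 7990), MFAP2 (97.1, 33 to 473), TSPYL5 (81.3, 39.3 to 203) and the replication fork helicase gene HLTF (75.3, 32.1 to 233). GABRQ, a GABA receptor subunit, fell from 33.1 ± 4.39 to 0.445 ± 0.0617 CPM. The total of 4485 was 2671 and 2312 without control replicates 1 and 2, and 2779 and 2798 without UVB replicates 1 and 2.

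Other groups moved in part after UVB. Filaggrin (FLG, log2 2.73 (SE 0.34)) and the desquamation protease KLK7 (1.71 (SE 0.21)) rose within the differentiation list, where 4 of 20 members rose and 1 fell (4 and 1 adjusted over the list alone). Fibronectin (FN1) rose by log2 4.63 (SE 0.75), with 3878 CPM in UVB replicate 1 and 869.9 in replicate 2. The mesenchymal transcription factor TWIST1 fell (log2 -2.90 (SE 0.43)), and in the mesenchymal list 5 of 14 members rose and 2 fell (6 and 2 adjusted over the list alone). Of ER stress genes, 6 of 20 members rose and 1 fell (6 and 1 adjusted over the list alone), led by the glutathione-degrading enzyme CHAC1 (3.10 (SE 0.24)) and the lipoprotein receptor VLDLR (2.75 (SE 0.36)). Of p53 targets, 0 of 24 members rose and 6 fell (0 and 6 adjusted over the list alone), among the lower ones the death receptor FAS (-0.70 (SE 0.11)), PHLDA3 (-0.72 (SE 0.09)) and SPATA18 (-1.35 (SE 0.28)). CDKN1A, the cell cycle inhibitor p21, was 81.5 ± 15.2 CPM in control and 106 ± 38.1 after UVB (adjusted p = 0.37). The prostaglandin synthase PTGS2 fell (log2 -1.75 (SE 0.24)) and the metalloproteinase inhibitor TIMP3 rose (1.62 (SE 0.22)). Camera called none of these lists: adjusted p was 0.198 for differentiation, 0.73 for mesenchymal genes, 0.136 for ER stress and 0.316 for p53 targets.

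NRF2 targets went both ways after UVB, and 7 of 33 members rose and 5 fell (7 and 5 adjusted over the list alone) (camera adjusted p = 0.992). The glutathione synthesis subunit GCLM rose (log2 0.80 (SE 0.14)) and epoxide hydrolase EPHX1 fell (-1.45 (SE 0.13)). SRXN1, which repairs peroxiredoxins, rose (0.41 (SE 0.10)), a call that ended without a library (control replicate 2 0.124, UVB replicate 1 0.0806, UVB replicate 2 0.0601). Not called were NQO1 (-0.19 (SE 0.12)), TXNRD1 (-0.19 (SE 0.18)), HMOX1 (1.98 (SE 1.09)), IL1B (-0.65 (SE 0.40)), MMP1 (0.78 (SE 0.64)), KRT1 (1.40 (SE 0.67)), KRT10 (0.43 (SE 0.15)) and the maintenance methyltransferase DNMT1 (0.27 (SE 0.16)).

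Camera called no list but activation after UVB. Members higher and lower follow, with those adjusted over the list alone in parentheses. For NRF2 targets they were 7 and 5 of 33 (7 and 5), for heat shock 6 and 0 of 17 (6 and 0), for ER stress 6 and 1 of 20 (6 and 1), for cholesterol synthesis 1 and 6 of 22 (1 and 8). For p53 targets they were 0 and 6 of 24 (0 and 6), for UV repair 1 and 1 of 22 (1 and 0), for mitosis 0 and 0 of 22 (0 and 0), for replication 4 and 0 of 22 (2 and 0). For inflammation they were 4 and 1 of 19 (4 and 1), for interferon response 0 and 0 of 26 (0 and 0), for differentiation 4 and 1 of 20 (4 and 1), for basal genes 3 and 1 of 16 (3 and 1). For mesenchymal genes they were 5 and 2 of 14 (6 and 2), for matrix proteolysis 3 and 1 of 16 (3 and 1), for immediate early genes 1 and 3 of 19 (1 and 3), for DNA methylation enzymes 0 and 0 of 14 (0 and 0). For histone enzymes they were 1 and 1 of 26 (1 and 1), for AHR targets 1 and 2 of 8 (2 and 3), for metallothioneins 0 and 2 of 5 (0 and 2), for hypoxia with glycolysis 9 and 4 of 20 (9 and 4). For oxidative phosphorylation they were 0 and 2 of 23 (0 and 1), for senescence 1 and 1 of 11 (1 and 1), for histones 4 and 0 of 13 (4 and 0), for fibroblast markers 0 and 0 of 4 (0 and 0). For endothelial markers they were 0 and 0 of 3 (0 and 0). Their camera adjusted p was 0.136 to 0.992. Median, mean and test differed in sign for NRF2 targets, interferon response, DNA methylation enzymes, AHR targets, senescence and fibroblast markers. Camera called 2 lists without control replicate 1, 5 without UVB replicate 1 and 2 without UVB replicate 2. With fry, which asks whether members move 1 way on balance, 7 lists were called, among them histones (0.0177), heat shock (0.0497) and p53 targets (0.0488). Of the untested lists, MITF, a melanocyte regulator, fell (log2 -0.62 (SE 0.15)), and the macrophage marker CD68 rose (1.00 (SE 0.27)), calls that ended without a library for CD68 (control replicate 1 0.106, control replicate 2 0.0877, UVB replicate 1 0.0802, UVB replicate 2 0.0811) and MITF (control replicate 1 0.0574, control replicate 2 0.0678, UVB replicate 2 0.103).

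The UVB differences were not spread evenly along the genome. Of 289 windows of 50 neighbouring genes, 59 passed the bound from shuffled positions (a median log2 of 0.3) after UVB, 56 in UVB+SFN against SFN and 58 in UVB+UA against UA, comparisons that share no library. In all 3, 43 windows passed, 25 higher and 18 lower. The 3 comparisons may still measure 1 difference between cell populations, since the labels do not say that unexposed cells were passaged in parallel. Genes of chromosome 1 from 154 to 213 Mb had a median log2 of -0.56 (400 genes, 89.5% on the lower side), and those along chromosome 14 one of 0.38 (483 genes). On chromosome 22 the median was -0.59 from 17.5 to 24.6 Mb and 0.62 from 30.8 to 51.2 Mb. For 50 genes at 54.5 to 56.2 Mb of chromosome 19 it was -1.1, with 100% on the lower side. SFN against control had 4 such windows, UA against control 0, UVB+SFN against UVB 1 and UVB+UA against UVB 2.

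With each window's shift, measured in the other pair of comparisons, taken out, an alternative chosen after seeing the data, 2895 genes were called after UVB, and 2390 of them were among the 4485. FAS (-0.29, adjusted p = 0.089), PHLDA3 (-0.20, 0.162), CD68 (0.75, 0.0813) and SRXN1 (-0.02, 0.908) were then not called. The same held for the histone genes HIST1H2AC (0.58, 0.0511), HIST1H2BD (0.31, 0.161) and HIST1H3D (0.72, 0.128) and for the heat shock genes HSP90AA1 (0.29, 0.0762), DNAJA1 (0.14, 0.28) and CHORDC1 (0.17, 0.21), members of lists called by fry, which was not run in this setting. Without this correction, the calls of these genes other than HSP90AA1 ended when a library was left out: HIST1H2AC (control replicate 1 0.0518, control replicate 2 0.058), HIST1H2BD (control replicate 1 0.0702, control replicate 2 0.107, UVB replicate 1 0.122), HIST1H3D (control replicate 1 0.168, control replicate 2 0.114, UVB replicate 1 0.208, UVB replicate 2 0.0597), DNAJA1 (control replicate 2 0.129, UVB replicate 1 0.094, UVB replicate 2 0.0613) and CHORDC1 (control replicate 2 0.234, UVB replicate 1 0.159, UVB replicate 2 0.101). With the correction KRT10 was called (0.63, 0.0162). TSHZ3, RIBC2, PTGS2 and TIMP3 lie in shifted windows and stayed called (5.44, 4.78, -1.32 and 0.91). The correction subtracted the shift of every window, also where it was under the bound. A call lost with it therefore does not place a gene in a shifted window. It also takes out any joint response of neighbouring genes, such as clustered histone genes, so a lost call does not show that a rise was regional. The activation list also stayed called (camera adjusted p = 6.37e-11), and higher ER stress (0.0196), differentiation (0.0344) and basal genes (0.0298) were called as well.

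**Figure D3:**
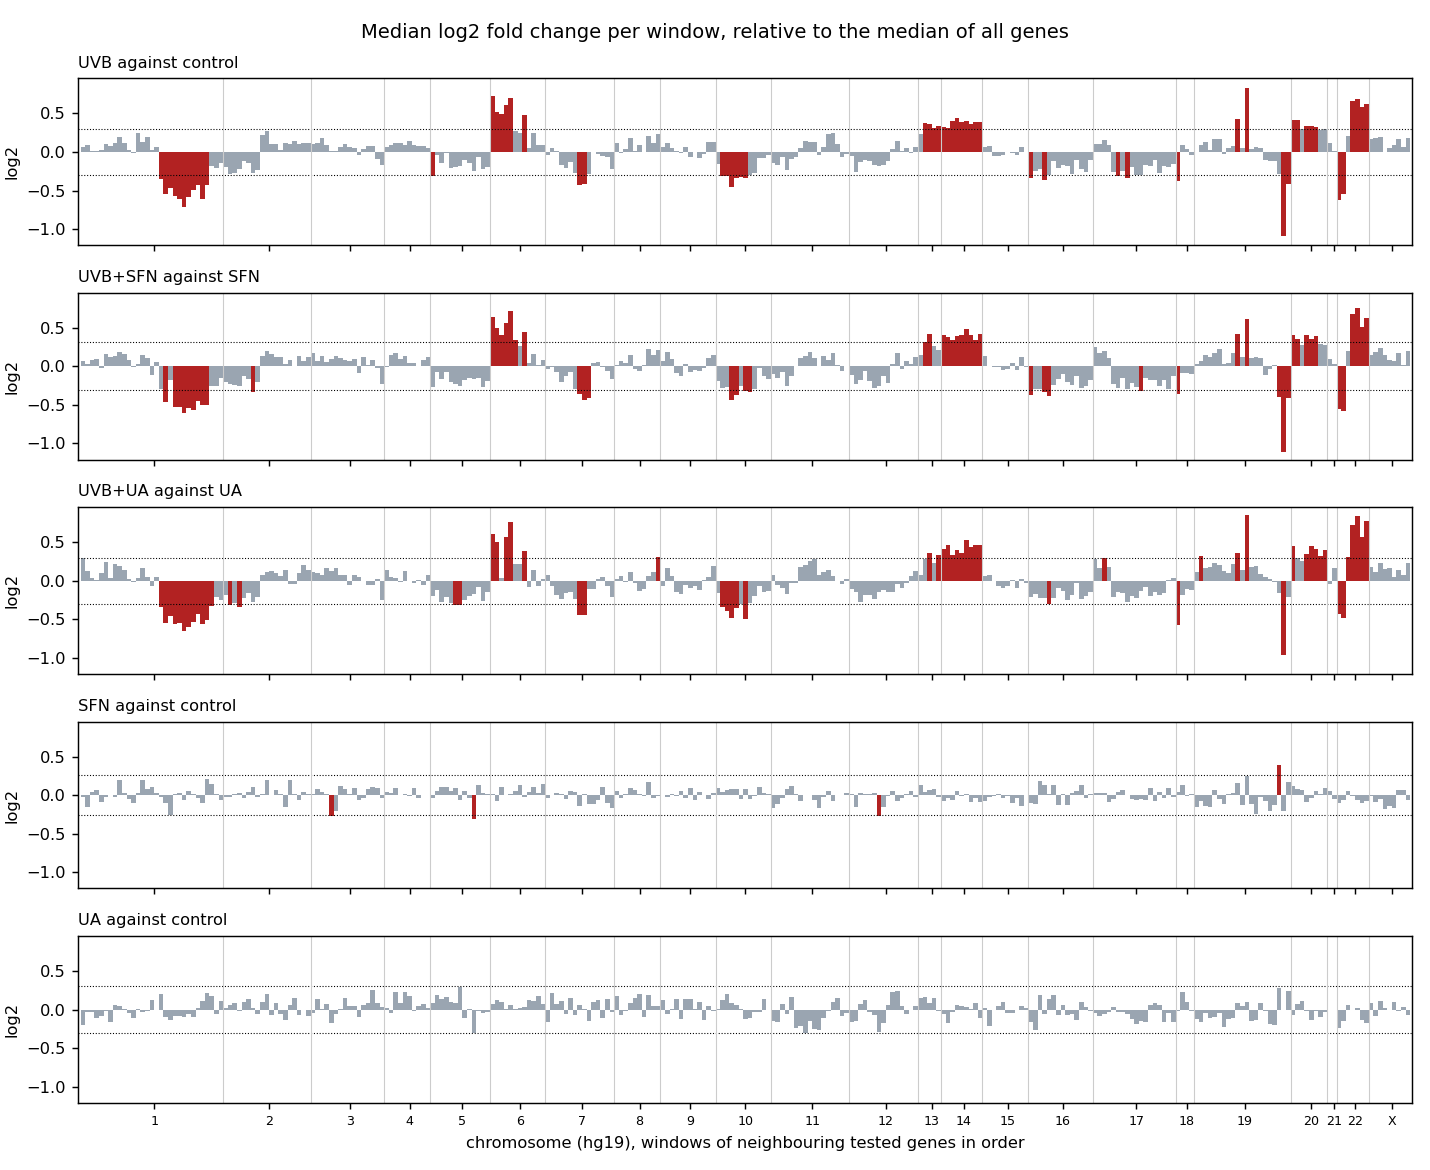
Median log2 fold change of each window of 50 neighbouring tested genes (hg19 order), relative to all genes, in 5 comparisons; red bars pass the dotted bound from shuffled positions. The 3 comparisons of exposed with unexposed cells have 56 to 59 such windows, and SFN and UA against control have 4 and 0.

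The SFN comparison asks what the compound does to unexposed cells, and the NRF2 programme was higher. Of NRF2 targets, 26 of 33 members rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 fold change of 0.96. NQO1, a quinone reductase and reporter of this pathway, went from 342 ± 5.28 to 880 ± 27 CPM, and the thioredoxin reductase TXNRD1 from 308 ± 34.8 to 953 ± 40.5 (SD, n = 2). SRXN1 went from 150.2 ± 13.3 to 573 ± 34.3 CPM and GCLM from 103 ± 16.3 to 259.7 ± 12.4. The aldo-keto reductases AKR1C3 (log2 4.72 (SE 0.31)), which shares sequence with AKR1C1 and AKR1C2, and AKR1B10 (3.03 (SE 0.25)) rose as well. The heme oxygenase HMOX1 was 1.1 ± 0.0538 CPM in control and 11.1 ± 1.89 with SFN, a call (adjusted p = 0.0489) that ended without any library of either group (control replicate 1 0.189, control replicate 2 0.223, SFN replicate 1 0.128, SFN replicate 2 0.173). Camera called the list (adjusted p = 5.91e-39, and adjusted p = 0.0346 with an estimated correlation).

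AHR targets were higher with SFN too: 4 of 8 members rose and 0 fell (6 and 0 adjusted over the list alone) (camera adjusted p = 4.66e-05, and adjusted p = 0.0429 with an estimated correlation). CYP1A1, the xenobiotic oxidase that reports AHR activity, went from 0.45 ± 0.421 to 15.3 ± 1.82 CPM, and NQO1 belongs to this list as well. Of heat shock genes, 8 of 17 members rose and 0 fell (10 and 0 adjusted over the list alone), such as the chaperones DNAJA1 (log2 0.74 (SE 0.08)) and HSP90AA1 (0.78 (SE 0.10)). The list's adjusted p was 5.13e-05, and adjusted p = 0.333 with an estimated correlation. Of cholesterol synthesis genes, 0 of 22 members rose and 9 fell (0 and 11 adjusted over the list alone), such as INSIG1 (-1.21 (SE 0.14)) and SC5D (-1.08 (SE 0.15)), at adjusted p = 1.55e-06, and adjusted p = 0.57 with an estimated correlation. Of the metal-binding metallothioneins, which share sequence, 0 of 5 members rose and 4 fell (0 and 4 adjusted over the list alone), such as MT1F (-1.49 (SE 0.20)) and MT1X (-1.11 (SE 0.17)). This gave adjusted p = 0.000499, and adjusted p = 0.251 with an estimated correlation.

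Further lists moved with SFN in unexposed cells. Of immediate early genes, 1 of 19 members rose and 7 fell (3 and 11 adjusted over the list alone), such as the AP-1 genes JUNB (log2 -1.23 (SE 0.20)) and JUND (-1.13 (SE 0.15)). The list was called at adjusted p = 0.00812, but not with an estimated correlation (adjusted p = 0.703) or without SFN replicate 1 (0.0789), without UA replicate 2 (0.109). Of histone genes, 5 of 13 members rose and 1 fell (7 and 1 adjusted over the list alone), such as HIST1H2BD (0.93 (SE 0.14)), at adjusted p = 0.0062, and adjusted p = 0.264 with an estimated correlation. This list was written as a sign of capture of RNA without poly(A) tails, so a difference in library preparation could move it too. Of fibroblast markers, 0 of 4 members rose and 3 fell (0 and 4 adjusted over the list alone), among them the collagen COL1A1 (20.2 ± 1.01 to 7.72 ± 0.821 CPM), which gave adjusted p = 0.00152, and adjusted p = 0.333 with an estimated correlation. Within lists that were not called, the basal keratin KRT15 (-2.43 (SE 0.25)), the chemokine CXCL1 (-2.62 (SE 0.31)) and the deacetylase HDAC6 (-0.83 (SE 0.10)) fell, and NFKB2 rose (1.48 (SE 0.23)). Of genes named in every comparison, CDKN1A (-0.39 (SE 0.29)), IL1B (0.33 (SE 0.39)), MMP1 (-1.24 (SE 0.68)), KRT1 (-2.04 (SE 0.74)), KRT10 (-0.07 (SE 0.15)) and DNMT1 (-0.02 (SE 0.16)) were not called.

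SFN changed 2824 genes against control, 1296 higher and 1528 lower (407 and 495 at least 2-fold). The largest rises were the lymphocyte receptor gene LY9 (ratio of counts and 95% interval 72, 27.7 to 267), the ubiquitin ligase MARCH4 (45.1, 23.4 to 99.5), TSPAN7 (40, 21.5 to 84.4), the long non-coding RNA LUCAT1 (0.197 ± 0.225 to 9.03 ± 0.0223 CPM), CYP1A1 and AKR1C3. The largest falls were the glycoprotein gene OLFM4 (32.4 ± 4.12 to 1.12 ± 0.709 CPM), ATP10B (5.47 ± 1.75 to 0.297 ± 0.165) and the disulfide isomerase AGR2 (50.8 ± 14.6 to 3.45 ± 1.3). With them fell the tight junction gene CLDN8 (9.84 ± 1.28 to 0.729 ± 0.139 CPM), PCDH18 (13 ± 0.816 to 1.03 ± 0.304) and PSG5 (29.6 ± 5.71 to 2.53 ± 0.505), which shares sequence with other PSG genes. Left-out libraries ended the calls of OLFM4 (control replicate 1 0.0612, control replicate 2 0.0782, SFN replicate 1 0.0968, SFN replicate 2 0.14), ATP10B (SFN replicate 1 0.0657) and PSG5 (control replicate 2 0.0742, SFN replicate 1 0.0809, SFN replicate 2 0.105). The total was 1260 and 562 without control replicates 1 and 2, 707 and 637 without SFN replicates 1 and 2, and 5137 without UA replicate 2, which here enters only the estimate of spread. With only the SFN and control libraries in the fit it was 6605.

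Lists not called with SFN had members higher and lower as follows, with those adjusted over the list alone in parentheses. For ER stress they were 4 and 1 of 20 (5 and 1), for p53 targets 2 and 5 of 24 (6 and 8), for UV repair 1 and 2 of 22 (2 and 4), for mitosis 3 and 0 of 22 (1 and 0). For replication they were 0 and 1 of 22 (0 and 1), for inflammation 7 and 4 of 19 (8 and 4), for interferon response 0 and 0 of 26 (0 and 0), for differentiation 1 and 7 of 20 (2 and 9). For basal genes they were 1 and 4 of 16 (3 and 6), for mesenchymal genes 2 and 2 of 14 (3 and 2), for matrix proteolysis 1 and 3 of 16 (2 and 3), for DNA methylation enzymes 1 and 2 of 14 (1 and 3). For histone enzymes they were 1 and 4 of 26 (1 and 4), for hypoxia with glycolysis 4 and 4 of 20 (7 and 4), for oxidative phosphorylation 0 and 0 of 23 (0 and 0), for keratinocyte activation 0 and 2 of 12 (0 and 2). For senescence they were 1 and 3 of 11 (2 and 3), for endothelial markers 0 and 0 of 3 (0 and 0). Their camera adjusted p was 0.0539 to 0.982. Median, mean and test differed in sign for interferon response, mesenchymal genes and histone enzymes.

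UA in unexposed cells came with lower cell cycle genes and higher ER stress genes. Of mitosis genes, 0 of 22 members rose and 22 fell (0 and 22 adjusted over the list alone), with a median log2 of -1.14: the spindle gene HMMR went from 138 ± 6.44 to 64.8 ± 14.3 CPM and the mitotic kinase PLK1 from 233 ± 23.2 to 91.6 ± 30.6 (SD, n = 2). Of DNA replication genes, 0 of 22 members rose and 20 fell (0 and 21 adjusted over the list alone), such as the polymerase POLA1 (log2 -0.69 (SE 0.13)) and the nuclease FEN1 (-0.93 (SE 0.18)). Of ER stress genes, 17 of 20 members rose and 0 fell (17 and 0 adjusted over the list alone): the stress transcription factor DDIT3 went from 17.4 ± 3.76 to 136 ± 52.4 CPM, CHAC1 from 2.14 ± 0.39 to 12.3 ± 2 and XBP1 from 88.5 ± 0.216 to 222 ± 58.9. Camera gave adjusted p of 1.33e-19, 1.72e-09 and 2.79e-15 for the 3 lists, and adjusted p = 0.363, 0.445 and 0.325 with an estimated correlation. UA replicate 2 differed from UA replicate 1 by a median log2 of -0.79, -1.1 and 0.61 in them.

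**Figure D4:**
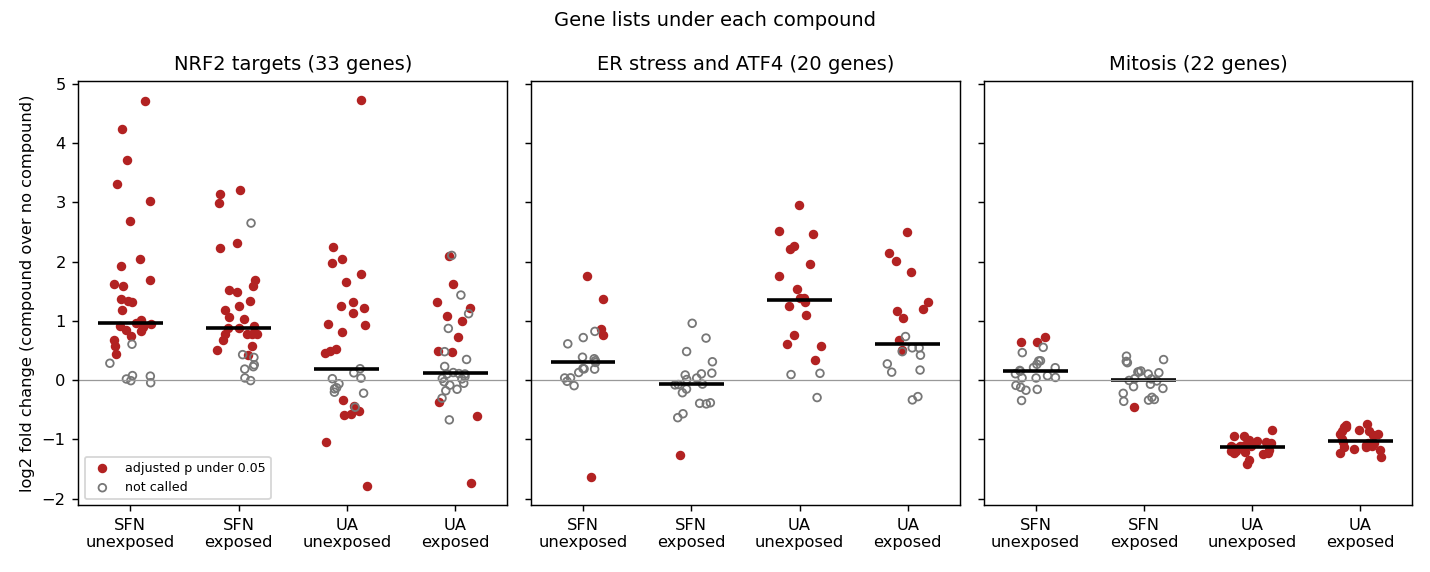
Log2 fold change of each member of 3 gene lists with SFN or UA against no compound, in unexposed and exposed cells; filled points have an adjusted p under 0.05, and bars are medians. NRF2 targets have medians of 0.96 and 0.89 with SFN and of 0.19 and 0.13 with UA, and mitosis genes medians of -1.14 and -1.03 with UA.

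Inflammatory and early response genes also moved with UA. Of inflammatory genes, 9 of 19 members rose and 1 fell (11 and 1 adjusted over the list alone): the cytokine IL1A went from 4.84 ± 0.545 to 71.5 ± 50.4 CPM and the NF-kB subunit RELB from 6.7 ± 1.55 to 42.1 ± 21.8, while CXCL1 fell (log2 -1.83 (SE 0.29)). Of immediate early genes, 9 of 19 members rose and 1 fell (9 and 1 adjusted over the list alone), such as ATF3 (2.26 (SE 0.33)) and KLF6 (2.18 (SE 0.34)). Of NRF2 targets, 16 of 33 members rose and 7 fell (16 and 8 adjusted over the list alone): the autophagy receptor SQSTM1 (2.05 (SE 0.24)), ferritin light chain FTL (1.79 (SE 0.21)) and TXNRD1 (1.33 (SE 0.18)) rose, AKR1B10 fell (-1.79 (SE 0.26)), and NQO1 was 348 ± 30.4 against 342 ± 5.28 CPM (adjusted p = 0.894). Camera gave adjusted p of 0.00053, 0.00879 and 0.0322, and adjusted p = 0.536 for each with an estimated correlation. Calls ended for immediate early genes without control replicate 1 (0.0777) and for NRF2 targets without control replicate 1 (0.0891). The UA libraries differed in the 3 lists by medians of 1.1, 0.85 and 0.29.

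Further called lists with more members lower than higher with UA were basal, differentiation, DNA methylation, cholesterol, oxidative phosphorylation and interferon genes. Of basal genes, 1 of 16 members rose and 8 fell (2 and 8 adjusted over the list alone), such as the keratins KRT14 (log2 -1.44 (SE 0.24)) and KRT15 (-1.53 (SE 0.24)), and of differentiation genes, 2 of 20 members rose and 10 fell (2 and 10 adjusted over the list alone), such as EVPL (-0.90 (SE 0.10)) and GRHL3 (-1.74 (SE 0.23)). Of DNA methylation enzymes, 0 of 14 members rose and 8 fell (0 and 8 adjusted over the list alone), led by DNMT1 (-0.81 (SE 0.17)). In cholesterol synthesis 0 of 22 members rose and 13 fell (0 and 18 adjusted over the list alone), in oxidative phosphorylation 0 of 23 members rose and 7 fell (0 and 10 adjusted over the list alone), and among interferon genes 1 of 26 members rose and 7 fell (1 and 11 adjusted over the list alone). Camera's adjusted p in this order was 0.0206, 0.00879, 0.0278, 2.06e-05, 0.000921 and 0.000507. It was 0.363 for the first 3 lists and 0.536 for the others, as adjusted p with an estimated correlation. Calls ended for basal genes without UA replicate 1 (0.149), differentiation without UA replicate 1 (0.149), interferon genes without UA replicate 1 (0.0578) and methylation enzymes without control replicate 1 (0.0708), without UA replicate 1 (0.0578). The UA libraries differed by medians of -0.15, -0.26, -0.055, -0.49, -0.26 and -0.53 in the same order.

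UA changed 4593 genes, 2320 higher and 2273 lower (751 and 532 at least 2-fold). The largest rises were higher in UA replicate 2 than in replicate 1. The stromelysin MMP3 had 1.09 and 85 CPM in them (ratio of pooled counts to control and 95% interval 2240, 401 to 88500), and the receptor IL1RL1 7.31 and 112 (1570, 433 to 12900). IL13RA2 had 0.0909 and 12.8 CPM (167, 45.7 to 1390), and the GTPase gene GEM 0.863 and 12.1 (84.7, 32.7 to 313). The cytokine CSF2 had 1.5 and 27.3 CPM against 0.2 ± 0.12 in control, and the antimicrobial RNASE7 26.9 and 149.5 against 2.56 ± 0.958. The largest falls were KRT1, a keratin of differentiating cells (14.2 ± 3.14 to 1.63 ± 1.04 CPM), FOXN1, a transcription factor of epidermal differentiation (6.36 ± 2 to 0.74 ± 0.146), and FREM2 (5.19 ± 0.0442 to 0.642 ± 0.0734). With them fell SAMD11 (101 ± 9 to 13.6 ± 8.38 CPM), KRT3 (6.86 ± 1.9 to 1.04 ± 0.841) and the desmosomal cadherin DSG4 (17.9 ± 5.58 to 3.04 ± 0.784). Left-out libraries ended the calls of MMP3 (control replicate 1 0.0638, control replicate 2 0.0703), IL13RA2 (control replicate 1 0.11, control replicate 2 0.139, UA replicate 2 0.813), GEM (control replicate 1 0.0647, control replicate 2 0.0581), CSF2 (control replicate 1 0.0562, control replicate 2 0.0708), KRT1 (control replicate 1 0.0543, control replicate 2 0.0843, UA replicate 1 0.0857, UA replicate 2 0.24) and SAMD11 (control replicate 2 0.0582, UA replicate 2 0.119).

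The call counts of UA depended on the libraries. The total was 1605 and 1281 without control replicates 1 and 2, 7448 without UA replicate 1 and 2591 without UA replicate 2. With only the UA and control libraries in the fit, edgeR called 0 genes. The main fit shares 1 estimate of spread over all groups, and the UA libraries differed most, so its adjusted p-values for UA may be too small. Of genes named in every comparison, HMOX1 (log2 4.72 (SE 1.03)), GCLM (0.52 (SE 0.14)), SRXN1 (0.45 (SE 0.10)) and IL1B (1.42 (SE 0.39)) rose. Left-out libraries ended these calls for HMOX1 (control replicate 1 0.0703, control replicate 2 0.0718), GCLM (control replicate 2 0.166, UA replicate 2 0.11), SRXN1 (control replicate 2 0.101) and IL1B (control replicate 1 0.114, control replicate 2 0.0978, UA replicate 2 0.273). CDKN1A (0.70 (SE 0.29)), MMP1 (1.71 (SE 0.64)) and KRT10 (0.28 (SE 0.15)) were not called. Within lists that were not called, the deacetylases HDAC9 (3.52 (SE 0.38)) and HDAC5 (1.16 (SE 0.21)), the angiogenic factor VEGFA (2.01 (SE 0.17)), the stress cytokine GDF15 (4.47 (SE 0.47)) and lipocalin LCN2 (3.15 (SE 0.34)) rose, and KRT6A fell (-1.22 (SE 0.19)).

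Lists not called with UA had these members higher and lower, with those adjusted over the list alone in parentheses. For heat shock they were 0 and 1 of 17 (0 and 1), for p53 targets 8 and 3 of 24 (8 and 3), for UV repair 3 and 4 of 22 (4 and 6), for mesenchymal genes 2 and 1 of 14 (2 and 1). For matrix proteolysis they were 6 and 2 of 16 (8 and 3), for histone enzymes 6 and 5 of 26 (6 and 5), for AHR targets 3 and 0 of 8 (3 and 0), for metallothioneins 1 and 0 of 5 (1 and 0). For hypoxia with glycolysis they were 6 and 3 of 20 (7 and 3), for keratinocyte activation 1 and 3 of 12 (1 and 3), for senescence 2 and 1 of 11 (2 and 1), for histones 4 and 1 of 13 (5 and 1). For fibroblast markers they were 0 and 1 of 4 (0 and 1), for endothelial markers 2 and 0 of 3 (2 and 1). Their camera adjusted p was 0.0643 to 0.641. Median, mean and test differed in sign for heat shock, UV repair, histone enzymes and metallothioneins. The endothelial marker CDH5 was 0.424 ± 0.0467 CPM in control and 3.16 ± 2.48 with UA.

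The next comparisons ask what each compound did to exposed cells. With SFN, the NRF2 programme was higher again, and 25 of 33 members rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 of 0.89. NQO1 went from 299.6 ± 47.5 to 682 ± 17.4 CPM, SRXN1 from 199 ± 1.82 to 571 ± 19.2 and TXNRD1 from 270 ± 16.7 to 808 ± 27.3 (SD, n = 2). AKR1C3 (log2 3.14 (SE 0.29)) and AKR1B10 (2.98 (SE 0.26)) rose too. Camera called the list (adjusted p = 2.66e-32, and adjusted p = 0.0483 with an estimated correlation). GCLM rose (0.67 (SE 0.14)), a call that ended without a library (UVB replicate 1 0.0548, UVB replicate 2 0.0928, UVB+SFN replicate 2 0.0971), and HMOX1 (2.65 (SE 0.90)) was not called.

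Further groups moved with SFN in exposed cells. Of inflammatory genes, 9 of 19 members rose and 2 fell (10 and 2 adjusted over the list alone), such as NFKB2 (log2 1.65 (SE 0.24)), at adjusted p = 0.00245, and adjusted p = 0.923 with an estimated correlation. IL1B rose (1.86 (SE 0.40)), a call that ended without a library (UVB replicate 1 0.1, UVB replicate 2 0.051, UVB+SFN replicate 2 0.114). Of metallothioneins, 0 of 5 members rose and 3 fell (0 and 3 adjusted over the list alone), such as MT1X (-1.28 (SE 0.17)), at adjusted p = 0.00245, and adjusted p = 0.279 with an estimated correlation. Of cholesterol synthesis genes, 0 of 22 members rose and 5 fell (0 and 5 adjusted over the list alone), such as INSIG1 (-0.73 (SE 0.14)), at adjusted p = 0.00245, and adjusted p = 0.976 with an estimated correlation. Fibroblast markers were 0 higher and 2 lower of 4 (0 and 3 adjusted over the list alone), with COL1A1 from 15.2 ± 5.45 to 5.72 ± 0.394 CPM, at adjusted p = 0.00245, and adjusted p = 0.49 with an estimated correlation. AHR targets were 3 higher and 0 lower of 8 (3 and 1 adjusted over the list alone), differentiation genes 1 higher and 7 lower of 20 (1 and 8 adjusted over the list alone), and interferon genes 4 higher and 0 lower of 26 (4 and 0 adjusted over the list alone). Their adjusted p was 0.0198, 0.0331 and 0.0243, and adjusted p = 0.279, 0.513 and 0.976 with an estimated correlation.

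List calls of SFN in exposed cells that ended were cholesterol synthesis without UVB+SFN replicate 1 (0.231), AHR targets without UVB+SFN replicate 1 (0.0786), differentiation without UA replicate 2 (0.0946), without UVB replicate 2 (0.0544), without UVB+SFN replicate 1 (0.0977) and interferon genes without UA replicate 2 (0.157), without UVB replicate 2 (0.797), without UVB+SFN replicate 1 (0.714). In the interferon list the direction turned without UVB replicate 2. Of 8 lists called, 4 were called without UVB+SFN replicate 1. Among p53 targets, a list that was not called, the death receptors FAS (log2 0.88 (SE 0.11)) and TNFRSF10B (0.91 (SE 0.13)) rose, and CDKN1A was 106 ± 38.1 CPM in UVB and 187 ± 43.7 in UVB+SFN (adjusted p = 0.077).

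SFN changed 2827 genes in exposed cells, 1488 higher and 1339 lower (340 and 452 at least 2-fold). With upper quartile scaling the split was 1166 and 1572, so which direction had more calls depends on the scaling. The largest rises were LUCAT1 (ratio of counts and 95% interval 28, 14 to 65.4), TSPAN7 (0.364 ± 0.0536 to 5.68 ± 2.61 CPM), IL1RL1 (1.53 ± 0.375 to 21.3 ± 9.1) and the hexokinase-like HKDC1 (0.48 ± 0.295 to 6.13 ± 0.892). With them rose the endotoxin receptor TLR4 (0.663 ± 0.369 to 8.43 ± 0.292 CPM) and the actin-bundling LCP1 (1.53 ± 0.296 to 18.8 ± 2.58). The largest falls were ATP10B (11.6 ± 4.48 to 0.841 ± 0.115 CPM), the estrogen sulfotransferase SULT1E1 (5.83 ± 0.0498 to 0.465 ± 0.375) and the stromelysin MMP10 (35.3 ± 25.7 to 3.62 ± 1.78). PSG5 (26.1 ± 26 to 2.71 ± 2.08 CPM), OLFM4 (26.2 ± 10.8 to 2.83 ± 3.88) and the kinase gene MAP2K6 (6.09 ± 1.93 to 0.682 ± 0.286) followed. KRT10 fell too (log2 -0.49 (SE 0.15)), and MMP1 (-1.47 (SE 0.66)), KRT1 (-1.88 (SE 0.68)) and DNMT1 (-0.06 (SE 0.16)) were not called. Left-out libraries ended the calls of LUCAT1 (UVB replicate 1 0.0588, UVB replicate 2 0.0503), IL1RL1 (UVB replicate 1 0.163, UVB replicate 2 0.19, UVB+SFN replicate 1 0.0569, UVB+SFN replicate 2 0.186), ATP10B (UVB+SFN replicate 2 0.0543), SULT1E1 (UVB+SFN replicate 2 0.0512), MMP10 (UVB replicate 1 0.0571, UVB+SFN replicate 2 0.0886), PSG5 (UA replicate 2 0.0588, UVB replicate 1 0.111, UVB+SFN replicate 2 0.122), OLFM4 (UA replicate 2 0.0959, UVB replicate 1 0.183, UVB replicate 2 0.0864, UVB+SFN replicate 2 0.153) and KRT10 (UVB replicate 1 0.069, UVB replicate 2 0.244, UVB+SFN replicate 2 0.322). The total was 1050 and 979 without UVB replicates 1 and 2, 485 without UVB+SFN replicate 2 and 4933 without UA replicate 2.

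Lists not called in UVB+SFN against UVB had these members higher and lower, with those adjusted over the list alone in parentheses. For heat shock they were 3 and 1 of 17 (3 and 1), for ER stress 0 and 1 of 20 (0 and 1), for p53 targets 6 and 5 of 24 (7 and 6), for UV repair 2 and 3 of 22 (3 and 3). For mitosis they were 0 and 1 of 22 (0 and 0), for replication 1 and 1 of 22 (1 and 1), for basal genes 4 and 4 of 16 (5 and 6), for mesenchymal genes 2 and 1 of 14 (2 and 1). For matrix proteolysis they were 5 and 3 of 16 (6 and 6), for immediate early genes 2 and 5 of 19 (2 and 6), for DNA methylation enzymes 1 and 3 of 14 (1 and 3), for histone enzymes 3 and 2 of 26 (3 and 3). For hypoxia with glycolysis they were 2 and 3 of 20 (2 and 3), for oxidative phosphorylation 0 and 0 of 23 (0 and 0), for keratinocyte activation 0 and 2 of 12 (0 and 2), for senescence 0 and 2 of 11 (0 and 2). For histones they were 1 and 1 of 13 (2 and 1), for endothelial markers 0 and 0 of 3 (0 and 0). Their camera adjusted p was 0.176 to 0.977. Median, mean and test differed in sign for heat shock, p53 targets, mitosis, basal genes, mesenchymal genes, matrix proteolysis, histone enzymes and hypoxia with glycolysis.

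UA in exposed cells came with lower mitosis, activation and differentiation genes and higher ER stress genes. Of mitosis genes, 0 of 22 members rose and 22 fell (0 and 22 adjusted over the list alone), with HMMR from 107 ± 14.6 to 45.3 ± 1.2 CPM. Of ER stress genes, 10 of 20 members rose and 0 fell (13 and 0 adjusted over the list alone), with DDIT3 from 11.7 ± 0.176 to 66.2 ± 4.87. Of activation genes, 1 of 12 members rose and 8 fell (1 and 9 adjusted over the list alone): SERPINB3 went from 4.59 ± 0.494 to 0.397 ± 0.328 CPM and S100A9 from 3.67 ± 2.12 to 0.0275 ± 0.0389, while LCN2 rose from 8.96 ± 0.0863 to 52.6 ± 7.18 (SD, n = 2). The call of S100A9 ended without a library (UVB replicate 2 0.0631, UVB+UA replicate 1 0.071, UVB+UA replicate 2 0.0588). Of differentiation genes, 1 of 20 members rose and 7 fell (1 and 9 adjusted over the list alone), with KRT4 from 106 ± 30.4 to 7.1 ± 3.03 CPM and KLK7 from 70.4 ± 21.6 to 26.1 ± 3.69. Camera gave adjusted p of 2.54e-20, 2.24e-09, 8.27e-06 and 3.88e-07, and adjusted p = 0.299, 0.289, 0.0606 and 0.0662 with an estimated correlation.

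Energy metabolism and further lists moved with UA in exposed cells. In oxidative phosphorylation 0 of 23 members rose and 13 fell (0 and 20 adjusted over the list alone), such as the ATP synthase subunit ATP5A1 (log2 -0.56 (SE 0.09)). Among hypoxia and glycolysis genes 8 of 20 members rose and 1 fell (9 and 2 adjusted over the list alone), with VEGFA at 1.45 (SE 0.17) and the glucose transporter SLC2A3 from 0.255 ± 0.207 to 4.04 ± 0.989 CPM. Replication genes were 0 higher and 2 lower of 22 (0 and 0 adjusted over the list alone), and heat shock genes 0 higher and 4 lower of 17 (0 and 9 adjusted over the list alone), such as HSPE1 (-0.61 (SE 0.09)). NRF2 targets were 9 higher and 3 lower of 33 (12 and 4 adjusted over the list alone), with SQSTM1 at 2.09 (SE 0.24) and AKR1B10 at -1.75 (SE 0.28). Inflammatory genes were 5 higher and 1 lower of 19 (8 and 1 adjusted over the list alone) and mesenchymal genes 3 higher and 1 lower of 14 (3 and 1 adjusted over the list alone). Camera's adjusted p in this order was 2.24e-09, 0.0149, 0.000258, 0.00381, 0.00677, 0.00275 and 0.0208. None was called at adjusted p = 0.4, 0.299, 0.563, 0.44, 0.48, 0.512 and 0.48 with an estimated correlation. Calls ended for NRF2 targets without UVB replicate 1 (0.234), hypoxia without UVB replicate 1 (0.0889) and mesenchymal genes without UVB replicate 2 (0.158).

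In exposed cells UA changed 2621 genes, 1405 higher and 1216 lower (484 and 235 at least 2-fold). The largest rises were KLHDC7B (0.391 ± 0.0152 to 10.9 ± 2.05 CPM), the estradiol-oxidising HSD17B2 (1.18 ± 0.362 to 26.7 ± 2.33) and RNASE7 (1.47 ± 0.377 to 29.7 ± 7.89). IL1RL1 (1.53 ± 0.375 to 24.3 ± 12.5 CPM), the leukocyte receptor gene SLAMF7 (0.551 ± 0.373 to 7.36 ± 0.891) and the collagen cross-linking enzyme LOX (1.3 ± 0.621 to 12.7 ± 1.06) followed. The largest falls were KRT1 (37.6 ± 12.4 to 0.988 ± 0.929 CPM), the secretoglobin SCGB1A1 (63.1 ± 1.65 to 3.61 ± 2.15), OLFM4 (26.2 ± 10.8 to 1.63 ± 2) and KRT4. The retinal dehydrogenase ALDH1A1 (25.2 ± 16.1 to 1.8 ± 0.0193 CPM) and KRT3 (5.41 ± 1.2 to 0.376 ± 0.221) fell as well. Left-out libraries ended the calls of RNASE7 (UVB replicate 2 0.0946, UVB+UA replicate 2 0.0509), IL1RL1 (UVB replicate 1 0.126, UVB replicate 2 0.209, UVB+UA replicate 1 0.079, UVB+UA replicate 2 0.16), KRT1 (UVB+UA replicate 2 0.0607), OLFM4 (UA replicate 2 0.071, UVB replicate 1 0.102, UVB replicate 2 0.0967, UVB+UA replicate 1 0.0712, UVB+UA replicate 2 0.176), ALDH1A1 (UVB+UA replicate 1 0.0506, UVB+UA replicate 2 0.0507) and KRT3 (UVB+UA replicate 2 0.0599). The total was 1640 and 297 without UVB replicates 1 and 2, 483 and 459 without UVB+UA replicates 1 and 2, and 5146 without UA replicate 2. With only the UVB+UA and UVB libraries in the fit it was 4544.

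Of genes named in every comparison, TXNRD1 (log2 1.08 (SE 0.18)), SRXN1 (0.48 (SE 0.10)), CDKN1A (1.08 (SE 0.29)) and IL1B (1.92 (SE 0.41)) rose with UA in exposed cells. Left-out libraries ended these calls for TXNRD1 (UVB replicate 2 0.0566), SRXN1 (UVB replicate 1 0.0558, UVB replicate 2 0.123, UVB+UA replicate 1 0.0643, UVB+UA replicate 2 0.119), CDKN1A (UVB replicate 2 0.239, UVB+UA replicate 1 0.12, UVB+UA replicate 2 0.151) and IL1B (UVB replicate 1 0.0746, UVB replicate 2 0.0738, UVB+UA replicate 2 0.0897). NQO1 (0.11 (SE 0.12)), HMOX1 (2.10 (SE 0.91)), GCLM (-0.05 (SE 0.14)), MMP1 (-0.26 (SE 0.64)), KRT10 (-0.45 (SE 0.15)) and DNMT1 (-0.43 (SE 0.17)) were not called. HDAC9 (2.56 (SE 0.36)) and HDAC5 (1.41 (SE 0.22)) rose within a list of histone enzymes that was not called.

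Lists not called in UVB+UA against UVB had these members higher and lower, with those adjusted over the list alone in parentheses. For cholesterol synthesis they were 0 and 1 of 22 (0 and 0), for p53 targets 8 and 3 of 24 (11 and 4), for UV repair 1 and 1 of 22 (1 and 0), for interferon response 1 and 2 of 26 (1 and 2). For basal genes they were 2 and 2 of 16 (4 and 4), for matrix proteolysis 2 and 2 of 16 (3 and 2), for immediate early genes 2 and 1 of 19 (5 and 1), for DNA methylation enzymes 1 and 2 of 14 (1 and 2). For histone enzymes they were 3 and 2 of 26 (4 and 2), for AHR targets 1 and 0 of 8 (3 and 0), for metallothioneins 1 and 0 of 5 (2 and 0), for senescence 2 and 1 of 11 (3 and 1). For histones they were 0 and 2 of 13 (0 and 2), for fibroblast markers 0 and 0 of 4 (0 and 0), for endothelial markers 1 and 0 of 3 (1 and 0). Their camera adjusted p was 0.0518 to 0.702. Median, mean and test agreed in sign for every list. Over the 5 main comparisons, the list calls that held with an estimated correlation were activation with UVB, NRF2 targets with SFN in unexposed and exposed cells, and AHR targets with SFN in unexposed cells.

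Whether a compound acted differently in exposed cells was tested as an interaction. The difference in CHAC1 was -2.39 (SE 0.32) on the log2 scale for SFN (adjusted p = 0.168) and -2.04 (SE 0.31) for UA (adjusted p = 0.196). For SFN it was -0.18 (SE 0.16) in NQO1, -0.41 (SE 0.15) in SRXN1 and -0.66 (SE 0.20) in GCLM (adjusted p = 1, 0.742 and 0.608). CHAC1, NQO1, SRXN1 and GCLM are shown here because they were named for the compounds, and their interactions were picked after the values were seen. CHAC1 was called for both compounds with DESeq2, with no filter and without UA replicate 2, for SFN with only the groups compared, and for UA without UA replicate 1. EdgeR called 0 genes for SFN and 0 for UA, with 886 and 1469 at an unadjusted p under 0.05, where chance gives 756. DESeq2 called 50 and 160, and limma-voom 0 and 0. Without UA replicate 2 the edgeR counts were 35 and 29, and without UA replicate 1 the UA count was 2240. In simulated data, edgeR recovered 54.1% of 2-fold SFN interactions, DESeq2 59% and limma-voom 51.9%. False calls over all folds were 15, 27 and 11 (7.58%, 11.4% and 5.88% of calls), so DESeq2's calls here are less certain. Those data had the same dispersion in every group, so the shares recovered may be too high for these libraries.

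Each compound's effects in unexposed and exposed cells could be compared without shared libraries. With SFN, 803 genes rose and 843 fell in both, where independent lists of these sizes would share 128 and 135. Only 2 went opposite ways (265 by independence), and fold changes correlated at 0.71 across genes. With UA, 979 rose and 792 fell in both (216 and 183 by independence) and 9 went opposite ways (398), with a correlation of 0.67. Across compounds, SFN in unexposed and UA in exposed cells shared 249 rises and 241 falls (120 and 123 by independence), with 177 opposite (246) and a correlation of 0.32. UA in unexposed and SFN in exposed cells shared 461 rises and 470 falls (228 and 201 by independence), with 148 opposite (430) and a correlation of 0.38.

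The series title names protection by sulforaphane as a question, so the genes changed by UVB were followed under each compound. Of 4485 genes called after UVB, 442 moved in the opposite direction with SFN in exposed cells and 599 in the same one (420 and 419 by independence). With UA, 497 moved opposite and 377 the same way (389 and 388 by independence). These comparisons share the UVB libraries, which by itself favours opposite moves: the covariance of fold changes was 0.0083 for SFN and -0.0454 for UA, against -0.0721 and -0.0668 with simulated unchanged groups. The simulation gave each gene the same dispersion in every group, although the groups differed in spread. The simulated covariances may therefore be too large or too small for the UVB libraries. With UVB calls from the other compound's arm, which shares no library, 467 moved opposite and 509 the same way with SFN, and 423 and 451 with UA. The opposite count for SFN was 242 and 241 without control replicates 1 and 2, 157 and 160 without UVB replicates 1 and 2, and 101 without UVB+SFN replicate 2. For UA it was 315 and 288 without control replicates 1 and 2, 326 and 54 without UVB replicates 1 and 2, and 116 and 110 without UVB+UA replicates 1 and 2.

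Exposed and unexposed cells were also compared within each compound. With SFN present the largest rises were LINC00665 (ratio of counts and 95% interval 133, 36.4 to 1100), the imprinting factor ZFP57 (36.2, 16.4 to 99.5) and ARHGEF6 (33.8, 16.9 to 78.9), and the largest falls SH3GL2 (658, 118 to 26000), GABRA3 (116, 60.9 to 255) and TSPYL5 (81.9, 42.9 to 180). With UA present the largest rises were IRX1 (62.7, 31.6 to 146), FN1 (92 ± 76.6 to 4355 ± 647 CPM) and ZNF626 (47.1, 19.9 to 147), which lies in a shifted window. The largest falls there were HLTF (125, 34.2 to 1040), SH3GL2 (57.9, 30.3 to 127) and MMP3 (log2 -6.77 (SE 1.64)), a call that ended without a library (UA replicate 2 0.12, UVB+UA replicate 1 0.0936, UVB+UA replicate 2 0.0803). UVB+SFN against SFN called 2276 genes higher and 2209 lower, and UVB+UA against UA 2288 and 2137 (620 and 908, and 720 and 680, at least 2-fold). With UVB against control the first shared 1545 rises and 1601 falls (331 and 334 by independence), with 7 opposite. The second shared 1463 and 1382 (333 and 323), with 13 opposite, and 2333 genes were called the same way in all 3. Nothing in the labels says that unexposed cells were passaged in parallel. The 3 comparisons may therefore measure 1 difference between cell populations, although they share no library. The first total (4485) was 2018 and 2390 without SFN replicates 1 and 2 and 2511 without UVB+SFN replicate 2. The second (4425) was 2360 and 2139 without UVB+UA replicates 1 and 2, and 818 with only its groups in the fit.

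The compounds, both given at the same dose per the labels, were compared directly. In unexposed cells AKR1B10 was 261 ± 16 CPM with SFN and 9.27 ± 1.55 with UA, the chemokine CCL5 12.9 ± 1.42 and 0.576 ± 0.534, and AKR1C3 342 ± 49.8 and 30.1 ± 13.1. The largest falls were MMP3, the aggrecanase ADAMTS5 (ratio of counts and 95% interval 40, 18.1 to 110) and IL1RL1. Calls of MMP3 (SFN replicate 1 0.116, SFN replicate 2 0.106, UA replicate 2 0.469) and IL1RL1 (SFN replicate 1 0.0852, SFN replicate 2 0.0772, UA replicate 2 0.0896) ended without a library. SFN against UA gave 2065 genes higher and 2152 lower (424 and 661 at least 2-fold). The total (4217) was 1695 and 1125 without SFN replicates 1 and 2, 6684 without UA replicate 1, and 124 with only these groups in the fit.

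In exposed cells the largest differences toward SFN were S100A9 (ratio of counts and 95% interval 258, 46 to 10200), AKR1B10 (184 ± 56.8 CPM with SFN and 6.95 ± 0.381 with UA) and the scavenger receptor MARCO (21.9, 11.4 to 48.4). The largest toward UA were PSG5 (2.71 ± 2.08 and 76 ± 18.2 CPM), C17orf107 (0.49 ± 0.014 and 8.11 ± 0.597) and MMP10 (3.62 ± 1.78 and 55.1 ± 0.597). UVB+SFN against UVB+UA gave 2226 genes higher and 2220 lower, and 318 and 885 at least 2-fold. The total (4446) was 2942 and 2199 without UVB+SFN replicates 1 and 2, and 1732 and 2211 without UVB+UA replicates 1 and 2.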

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

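The gene lists were written before the data were examined. Their tests were planned for the main comparisons, and the list tests of the interactions were added to that plan. The tests of the regional pattern and of depth between the UA libraries were chosen only after the result was seen.

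These gene lists drew attention because a compound's effect on them, relative to other genes, differed between exposed and unexposed cells by camera with the preset correlation. None was called with an estimated correlation (adjusted p = 0.185 or more for SFN and 0.0757 or more for UA). No single gene was called by edgeR (886 and 1469 at an unadjusted p under 0.05) or limma-voom, and 50 and 160 were by DESeq2. For SFN the effect was lower in exposed cells for ER stress (adjusted p = 9.49e-07, median log2 difference -0.29), heat shock (7.13e-06, -0.29) and histones (0.000983, -0.38). It was also lower for AHR targets (0.00551, -0.39), mitosis (0.00551, -0.23) and NRF2 targets (0.00602, -0.06). It was higher for basal genes (0.000632, 0.32), interferon genes (0.000662, 0.39), cholesterol synthesis (0.00602, 0.08), inflammation (0.0263, 0.17) and matrix proteolysis (0.043, 0.00496).

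For UA the effect was lower in exposed cells for histones (6.64e-06, -0.55), ER stress (1.89e-05, -0.34), heat shock (0.00276, -0.22), immediate early genes (0.00849, -0.31), differentiation (0.012, -0.33) and oxidative phosphorylation (0.0127, -0.15). It was higher for interferon genes (2.89e-06, 0.71), basal genes (6.64e-06, 0.39), replication (5.34e-05, 0.42) and cholesterol synthesis (0.000173, 0.29). UA replicate 2 differed from replicate 1 by a median log2 of -1.1 in replication, -0.53 in interferon, -0.49 in cholesterol, 0.61 in ER stress and 0.85 in immediate early genes. These gaps are larger than the median differences given, except in interferon genes. The UA group rests on both libraries, so a gap enters the difference only in part. Replicate 2 may account for part or all of some of these differences, and how much was not tested. The gap was smaller in basal genes (-0.15) and heat shock (0.15). In histones (-0.033), differentiation (-0.26) and oxidative phosphorylation (-0.26) it ran toward a higher effect in exposed cells, opposite to the difference given. With fry, the basal (0.0151) and histone (0.0361) lists were called for UA, and none for SFN.

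The UA libraries differed more from each other than those of any other group. A difference in depth would leave the 1320 genes over 2-fold apart near the floor, but 39.5% of them had a mean of 5 CPM or more. RNA of another cell type would bring its markers. By a rule written before the test, 0 markers of fibroblasts, melanocytes, leukocytes or endothelial cells were both at 5 CPM in replicate 2 and over 2-fold above replicate 1, where the highest of each list in replicate 2 were COL1A1 (15.2 CPM), MITF (43.4), CD68 (16) and CDH5 (4.91). But 2 of 3 tested endothelial markers were over 2-fold higher in replicate 2 (median log2 difference 1.1), CDH5 lies close under the bound, and 2 leukocyte markers had a median of 0.7, so a small share of such RNA is not excluded. A stronger response in replicate 2 may account for part of it: over the 2621 genes called for UA in exposed cells, the change from control followed that effect with a slope of 0.544 in replicate 1 and 0.811 in replicate 2, a ratio of 1.49. Why 1 library would respond more stays open, since the labels give no batch, dose or time that differs between them.

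Genes of large regions differed together between exposed and unexposed cells, in 43 windows at the same places in 3 comparisons that share no library (correlation of window shifts 0.925 to 0.968). After trends in GC content and gene length were removed, with GC values for 93.8% of genes, 100% of these windows stayed past the bound. Windows were picked by their median, which a few strongly regulated neighbours do not move. The median share of 86% of genes on the window's side, in windows picked in the other comparisons, is therefore no separate test of such neighbours. A hypothesis that stays open is that the exposed cells may carry other copy numbers of these regions, HaCaT being an aneuploid line: the shift was 0.43 in higher-expressed and 0.48 in lower-expressed genes (ratio 0.906). No DNA was analysed here, and every exposed library differs from every unexposed one in exposure, so whether such a difference would come from UVB or from separately kept cells was not tested. If the cells were kept separately, the 3 comparisons may measure 1 difference between cell populations, although they share no library.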

How the results depend on the processing

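The regional correction was chosen after seeing the data. So were the fits without UA replicate 2 for comparisons that do not hold the unexposed UA group, such as UVB+UA against UVB. The other alternatives were fixed before the data were examined. Counts of called genes follow in the order UVB, SFN and UA against control, UVB+SFN and UVB+UA against UVB, UVB+SFN against SFN, UVB+UA against UA, SFN against UA, and UVB+SFN against UVB+UA. With a log2 change of at least 1 they were 1547, 902, 1283, 792, 719, 1528, 1400, 1085 and 1203. At an adjusted p under 0.01 they were 2412, 905, 1557, 863, 668, 2317, 2231, 1703 and 1988, fewer by construction. Leaving out 1 library gave 2312 to 6502, 562 to 5137, 1281 to 7448, 485 to 4933, 297 to 5146, 2018 to 6576, 2139 to 6297, 1125 to 6684 and 1732 to 6590. With only the groups compared in the fit, counts that moved over 1.5-fold were SFN 6605, UA 0, UVB+UA against UVB 4544, UVB+UA against UA 818 and SFN against UA 124. Those that fell all hold the unexposed UA group. Its replicates differed most (SD of log2 differences 0.591, against 0.282 to 0.417 in the other groups), while the main fit shares 1 spread. Adjusted p-values of the main fit may thus be too small for comparisons with this group and too large for others. How much of the moves this accounts for was not tested. DESeq2, limma-voom, the other scalings and filters and non-robust estimation kept these 9 totals within 1.5-fold. Upper quartile scaling moved the balance of higher and lower calls: 1166 and 1572 for UVB+SFN against UVB, 1846 and 2616 for UVB+SFN against SFN, 1990 and 2497 for UVB+UA against UA, 2593 and 1962 for UA, 1853 and 2392 for SFN against UA and 1839 and 2453 for UVB+SFN against UVB+UA. Interactions had 0 calls, but 2 (SFN) and 3 (UA) without a filter, 50 and 160 with DESeq2, 9 for SFN with only the groups compared, and 0 to 35 and 0 to 2240 with 1 library left out; the cause was not tested. UVB calls moved back were 90 (SFN) and 107 (UA) at 0.01, and 101 to 300 and 54 to 326 with 1 library left out.

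With the regional shift removed, UVB called 2895 genes, and ME1, SREBF2 and SRXN1 turned sign (log2 -0.0114, -0.0475 and -0.0227, adjusted p = 0.944, 0.766 and 0.908), since the window's shift was subtracted. Lists called after UVB were 1, but 3 without a filter, 7 with fry and 4 with the regional shift removed. With an estimated correlation, 2 lists were called for SFN, 0 for UA, 1 for UVB+SFN and 0 for UVB+UA against UVB, in place of 8, 12, 8 and 11. Of the 40 list calls of the 5 main comparisons, 14 ended with fry, 4 without a filter and 1 with upper quartile scaling. With 1 library left out, the lists called were 1 to 5 for UVB, then 7 to 10, 9 to 13, 4 to 9 and 11 to 13. The interferon list in UVB+SFN against UVB had an adjusted p of 7.93e-16 without UVB replicate 1 and turned direction without UVB replicate 2 (0.797). Of 494 named gene calls, most ended and 0 turned sign with some library left out, while 5 ended with DESeq2 and 60 without a filter. With the regional shift removed, 21 of 88 calls for UVB ended with their sign kept. A further 3, ME1, SREBF2 and SRXN1, ended and turned sign. With only the groups compared 130 of 488 ended. Of the named genes not called in a comparison, counted once per comparison, 88 became called with some library left out, 38 with DESeq2, 67 with only the groups compared, 8 without a filter and 5 with the regional shift removed.

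In the labels, same-numbered libraries of different groups share only the number. Their deviations correlated at -0.068 to 0.3 over 15 pairs of groups, 11 of them over 0.1. In 12 of 12 libraries the correlation was highest with their own number, a hint from the data and not the design, and the libraries of a group mirror each other here, so they are not separate evidence. With the number as a block, calls higher and lower were 2362 and 2489 for UVB, 1486 and 1737 for SFN, 2456 and 2508 for UA, 1611 and 1570 for UVB+SFN and 1649 and 1368 for UVB+UA against UVB, and 0 for both interactions. Of the named genes not called in a comparison, 39 became called under the block, and 1 call ended. Depth limits genes near the floor, whose ratios have wide counting intervals.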

Other observations

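The simulation of unchanged groups with shared UVB libraries was chosen only after the result was seen. The genes of the next paragraph were picked from the named ones after their values were seen, and only their levels are given.

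HDAC9, a class IIa histone deacetylase, was 17.8 ± 2.96 CPM in control, 75.4 ± 3.52 with SFN and 204 ± 120 with UA, and 31.7 ± 0.639, 133 ± 41 and 187 ± 20.6 in the exposed counterparts (SD, n = 2). HDAC6, a cytoplasmic deacetylase, was 48.2 ± 3.2, 27.1 ± 0.106 and 45.6 ± 2.84 CPM in unexposed cells and 63 ± 3.04, 36.1 ± 0.849 and 60.6 ± 5.52 in exposed ones. The angiogenic factor VEGFA was 48.1 ± 1.17, 96.5 ± 3.96 and 194 ± 47.1 CPM, and 76.7 ± 12.2, 159 ± 20.6 and 210.1 ± 9.83 after UVB.

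SFN and UA against control, which share the control libraries, had 489 rises and 625 falls in common and 109 opposite calls (199, 230 and 430 for independent lists). The covariance of their fold changes was 0.3, of which simulated unchanged groups with shared controls gave 0.0472. UVB+SFN and UVB+UA against UVB, which share the UVB libraries, had 336 rises and 274 falls in common and 119 opposite calls (138, 108 and 244 for independent lists). The covariance of their fold changes was 0.185, of which simulated unchanged groups with shared UVB libraries gave 0.0627. The simulations gave each gene the same dispersion in every group, while replicates differed by an SD of log2 differences of 0.282 in control and 0.417 in UVB. The simulated covariances are approximate for that reason. Part of the overlap in both pairs may come from the shared libraries.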
